A study of Mus musculus with 9 samples.

How the data were processed

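Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done, per the labels, on 3T3-L1 cells, a mouse preadipocyte line that can be differentiated into adipocytes. The cells received a negative control siRNA or an siRNA against ME1 or ME2, and adipocyte differentiation was induced 2 days later. They were fixed with 1% formaldehyde 7 days after induction, and the chromatin was sheared to about 200 to 1000 bp. Antibodies were against acetylated histone H3 (AcH3), acetylated histone H2B (AcH2B) and the histone deacetylase HDAC3. The 9 libraries were grouped by the antibody and siRNA labels, which gave 1 library for each of the 9 combinations. The titles of the 3 HDAC3 libraries name H3 and not HDAC3, and the antibody label was followed.

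The values start from 1 deposited table of peaks per library, called library by library as far as the labels say. BWA, SAMtools, MACS2, bedtools and deepTools are named in the submitters' processing notes, and their versions, parameters, roles and order are not given in the sources used here. The deposited tables have 10 columns without a header, laid out as MACS2 writes them, and the meaning of each column was read from the values. The deposited pileup at each summit is a coverage signal, in fragments scaled to a common depth with a background library. The deposited significance of a summit is a −log10 p-value against the local background and a −log10 q-value. The deposited fold enrichment is the ratio of pileup plus 1 to local background plus 1 at the summit, and it is the authors' own value for that peak. It is lower than the plain ratio where the background is low. The acetylated histone lists had been limited on q, with a lowest −log10 q of 1.30. The HDAC3 lists had been limited on p, with a lowest −log10 p of 2.30, and most HDAC3 peaks had a q above 0.05. Peaks with several summits were treated as 1 region, scored by the highest −log10 p.

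The submitters' processing notes name the build mm8. The scaffold names in the deposited tables belong to GRCm38, the last region on chromosome 1 ended at base 195321056, and 53.0% of AcH3 siControl regions lay within 1 kb of a gene end of the GRCm38.p6 RefSeq gene table, against 10.4% of the same regions shifted by 50 kb. The coordinates were therefore read as GRCm38, counted from 1. The gene table gives no strand or exons, so the start of a gene could not be told from its end. The planned promoter call was replaced by a region within 1 kb of either annotated end of a gene, called an end region below, and locations were split into gene ends, gene bodies and the space between genes. This differs from the design written before the data were examined, in which promoters, exons and introns were to be used. It covered 21883 protein-coding genes.

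Depth was recovered from the deposited values. Pileups came in steps of constant size, which gave the scaling, and the background at each summit was worked out from pileup and fold. A Poisson p-value recomputed from these differed from the deposited −log10 p by at most 0.000292 for 99% of summits in each library. Divided by the estimated fragment length, the genome background gave the fragments per kb of mappable genome. The background depths of the AcH3 and AcH2B libraries of one siRNA were 7.55 and 7.55 for siControl, 7.67 and 7.67 for siME1 and 7.08 and 7.08 for siME2, so both antibodies appear to have been set against 1 background library per siRNA.

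Regions overlapping by 1 bp or more counted as shared, and the chance level was the mean of 100 rotations of one list along the chromosomes. A gene was called gained if it had an end region in a knockdown library and none in the siControl library of that antibody, and lost in the reverse case. An end region had to overlap the window by 1 bp only, so it could lie mostly outside the window or belong to a neighbouring gene. A region that was still present but narrower or shifted could therefore be called lost. With 1 library per antibody and siRNA there was no replicate, no test across conditions was possible, and every difference describes these libraries. Intervals are Wilson 95% intervals of counts and cover counting error only. Genes lost in both knockdowns share the siControl library, so 100 unchanged libraries were also simulated from the siControl summits, at the depth and threshold of each knockdown library, with Poisson counts either around the observed count or around a value 1 SD below it. The simulated regions kept their siControl coordinates, so no gene could be lost there through a narrower or shifted region. Genes gained cannot be simulated this way.

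Before the data were examined, 20 gene lists, the alternatives and the rule for naming genes were fixed. The lists held 403 distinct genes, and 1 symbol did not match the gene table. They covered adipocyte genes, fatty acid and triglyceride synthesis, cholesterol synthesis, NADPH-producing enzymes, NRF2 and redox genes, the HDAC3 and NCoR complex, acetyltransferases and deacetylases, preadipocyte and fibroblast genes, mitochondrial oxidation and thermogenesis, insulin signalling, the circadian clock, immediate early and inflammatory genes, the cell cycle, constitutively used genes, and genes of neurons, hepatocytes, muscle, leukocytes, endothelium, and bone and cartilage. List names are labels fixed beforehand, and the NADPH-producing list also holds enzymes that do not make NADPH themselves, such as Pgls and Taldo1. The number of list members with an end region was ranked among 10000 random lists of the same size. For a knockdown, these were matched on the siControl call and on the siControl score of the same antibody.

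The named genes were Me1, Me2, Hdac3, Ncor1, Pparg, Cebpa, Fabp4, Adipoq, Plin1, Lpl and Fasn. For each list and antibody, up to 4 genes lost in both knockdowns and up to 4 gained in both were added by score. For each antibody, the 5 highest-scoring genes lost in both, the 5 gained in both and the 3 highest-scoring genes of the siControl library were added as well. Some genes that the rule names are not reported here.

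The alternatives were a stricter score limit (the median siControl score of the antibody), equal numbers of top-scoring regions, regions within 1 kb joined, a reciprocal overlap of 50%, and windows of 2.5 and 10 kb. After the data were seen, a region anywhere in the gene, and the removal of mitochondrial and scaffold regions and of regions whose background was over 3 times that of the genome, were added. The gene call step was tested on simulated data: of 200 genes given planted regions among the 21883 tested, 100% were recovered. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.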

Results

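The labels describe a study of NADPH, malic enzymes and histone acetylation in differentiating fat cells. ME1 is a cytosolic malic enzyme that makes NADPH from malate, and ME2 is a mitochondrial malic enzyme that mainly makes NADH. Acetylated histones mark active chromatin, and HDAC3 is the deacetylase of the NCoR corepressor complex. The 9 libraries, 1 for each antibody and siRNA, address whether the genomic positions of AcH3, AcH2B and HDAC3 differed after knockdown of either enzyme. There were no replicates, so each difference is one between 2 libraries and no spread between cultures is known.

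The estimated ChIP depth was 6.75, 8.38 and 7.36 fragments per kb of mappable genome for AcH3 in siControl, siME1 and siME2. For AcH2B it was 8.42, 8.40 and 8.13, and for HDAC3 it was 6.04, 7.27 and 7.79. The transcripts of Me1 and Me2 were not measured, so the extent of knockdown is not checked by these data. At Me1, AcH3 end regions were listed in all 3 libraries, with folds over background of 15.4 in siControl, 8.27 in siME1 and 3.87 in siME2. At Me2, AcH3 end regions were listed in siControl, with a fold of 8.23, and siME1, with a fold of 4.14, and not in siME2.

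AcH3 was listed at fewer gene ends in both knockdowns than in siControl. End regions were found at 10292 genes in siControl, 9129 in siME1 and 5221 in siME2. Of the 10292 genes marked in siControl, 1322 had no AcH3 end region in either knockdown. Among them were Klf5 and Ebf2, transcription factors of adipocyte differentiation, Dlk1, a preadipocyte marker, Kat2a, a histone acetyltransferase, and Ccne1, which encodes cyclin E1. The adipocyte and preadipocyte lists were marked more often in siME2 than matched lists (percentiles 99.6 and 99.9). So were constitutively used (99.9), immediate early and inflammatory (99.95) and insulin signalling genes (99.5), so this was not particular to fat-cell genes. AcH2B was not matched. In siME1 the adipocyte and preadipocyte lists lay near the middle of matched lists (55.6 and 55.5). Regions away from gene ends were more numerous in the knockdowns, at 23757 in siME1 and 22354 in siME2 against 10346 in siControl. With the stricter score limit, a split added after the data were seen, they numbered 3921 and 2651 against 2377, or 1.65 and 1.12 times as many. The siME2 library stood apart from the siControl library in fold as well: over 4673 regions shared by all AcH3 and AcH2B lists, its folds had a Spearman rho of 0.19 with AcH3 siControl and 0.46 with AcH2B siME2. AcH3 siME2 and AcH2B siME2 appear to share a background library, which enters both folds.

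In siME1, 1446 genes had lost and 283 had gained an AcH3 end region relative to siControl, so that 16.4% of the genes that differed were gained (interval 14.7% to 18.2%). In siME2, 5305 had lost and 234 had gained one, or 4.22% gained (3.73% to 4.79%). With the stricter score limit, lost and gained genes numbered 4026 and 134 in siME1 and 7715 and 61 in siME2. Without high-background regions they numbered 1505 and 666 in siME1 and 5192 and 483 in siME2. Unchanged libraries simulated 1 SD below the observed counts lost at most 257 genes at the depth of siME1 and 325 at the depth of siME2. The share of regions within 1 kb of a gene end was 53.0% in siControl, 31.7% in siME1 and 21.3% in siME2. The same regions shifted by 50 kb gave 10.4%, 7.33% and 6.54%.

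**Figure D1:**
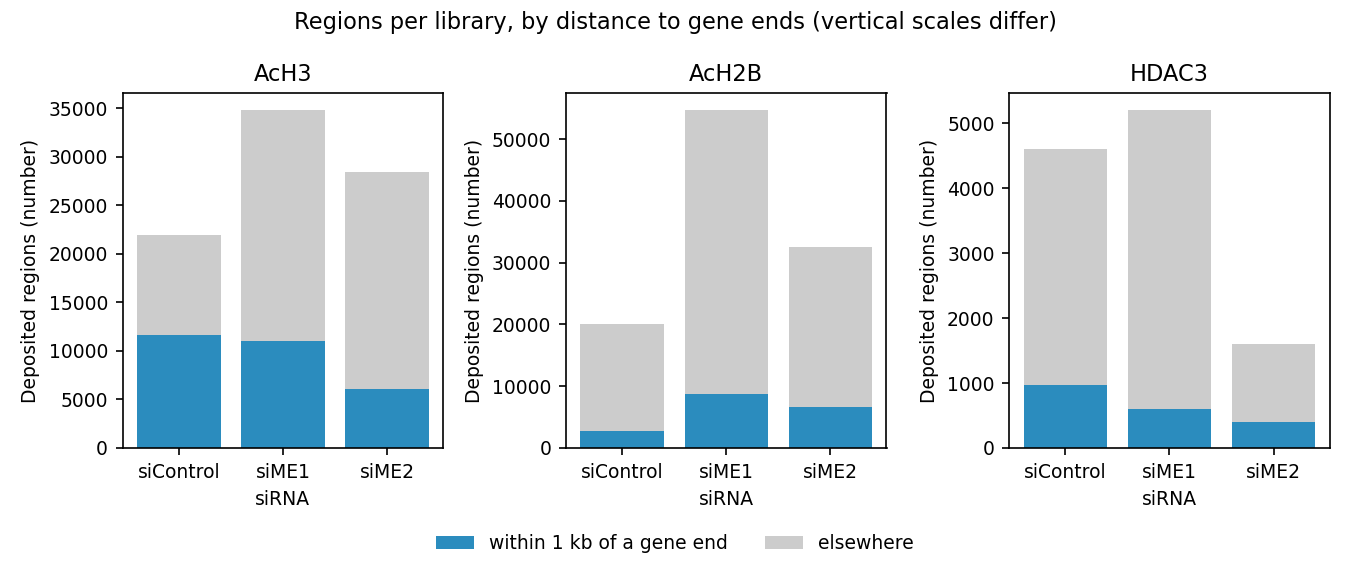
Number of deposited regions per library (vertical axis) for each siRNA (horizontal axis), split into regions within 1 kb of a gene end (blue) and elsewhere (grey), with 1 panel per antibody and a separate vertical scale in each. AcH3 regions near gene ends numbered 11645 in siControl and 6057 in siME2, while AcH2B regions near gene ends numbered 2667 in siControl and 8681 in siME1.

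The deposited AcH3 lists held 21995 regions in siControl, 34799 in siME1 and 28415 in siME2, covering 20.6, 23.7 and 16.2 Mb. The ratios to siControl were 1.58 and 1.29. Median fold over background was 5.82, 4.34 and 4.19, and median width 689, 504 and 440 bp. Of the siControl regions, 71.1% overlapped a region of siME1 (70.5% to 71.7%) and 46.5% one of siME2 (45.9% to 47.2%), against 2.01% and 1.53% after rotation. With the stricter score limit, the ratios of region number were 0.801 and 0.358, the reverse of the ratios for all deposited regions. The share gained in siME1 ranged from 3.22% with that limit to 30.7% without high-background regions.

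By gene list, fewer members of the metabolic lists carried an AcH3 end region in siME2 than in siControl, as over all genes, and the numbers were near or above the medians of matched lists. Of 20 NADPH-producing enzyme genes, 17 had an AcH3 end region in siControl, 14 in siME1 and 9 in siME2 (matched median 8, percentile 69.7). Aldh1l2, of mitochondrial folate metabolism (siControl fold 8.39), Taldo1, of the pentose phosphate pathway (4.37), and Me3, the third malic enzyme gene (4.41), had none in either knockdown. Of 20 cholesterol synthesis genes, 17, 14 and 10 were marked in siControl, siME1 and siME2 (siME2 median 8, percentile 77.3), with Dhcr7 (9.06) and Nsdhl (5.58) lost in both. Of 19 NRF2 and redox genes, 16, 14 and 8 were marked (median 8, percentile 49.0), with the mitochondrial peroxiredoxin gene Prdx3 (7.19) and Gclc (4.86) lost in both. Of 20 mitochondrial oxidation and thermogenesis genes, 14, 13 and 6 were marked (median 7, percentile 36.2), and Ppargc1a (4.08), a coactivator of mitochondrial biogenesis, was lost in both. Of 20 fatty acid and triglyceride synthesis genes, 14, 14 and 10 were marked (median 7, percentile 95.8). In siME1, losses with equal numbers of regions were 5 against 3 for NADPH producers and for cholesterol synthesis, 3 against 1 for mitochondrial genes and 3 against 0 for fatty acid synthesis, which had 2 gained and 0 lost within 10 kb.

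Of 34 adipocyte genes, 15 carried an AcH3 end region in siControl, 13 in siME1 and 12 in siME2. The siControl number lay at percentile 36.5 of random lists. The siME2 number lay at percentile 99.6 of lists matched on siControl calls and scores, whose median was 7 genes. Klf5 (siControl fold 6.00) and Ebf2 (5.07) were lost in both knockdowns. The nuclear receptor gene Pparg had folds of 7.14 and 3.48 in siControl and siME1 and no end region in siME2. The transcription factor gene Cebpa was listed in all 3, at 6.45, 3.86 and 4.15, as was the fatty acid synthase gene Fasn, at 11.9, 9.28 and 6.00. The strongest end region of the lipoprotein lipase gene Lpl had folds of 7.26 and 4.96 at 1 gene end in siControl and siME1 and of 4.50 at the other end in siME2. Fabp4, a fatty acid binding protein gene, was listed only in siME2 (3.62), and no library of any antibody had a region in or within 1 kb of Adipoq, which encodes adiponectin, or Plin1, which encodes the lipid droplet protein perilipin.

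Of 24 preadipocyte and fibroblast genes, 17, 16 and 16 were marked by AcH3 in siControl, siME1 and siME2, and the siME2 number lay at percentile 99.9 of matched lists. Dlk1 (12.3) was lost in both. Constitutively used genes were marked at 24, 24 and 21 of 25 (percentile 99.9 for siME2), insulin signalling genes at 17, 16 and 14 of 18 (99.5), and immediate early and inflammatory genes at 17, 15 and 14 of 20 (99.95). Tbc1d4 (5.60), of insulin-stimulated glucose uptake, and the immediate early genes Fosb (5.24) and Atf3 (4.66) were lost in both. Cell cycle genes were marked at 20, 15 and 11 of 22, with Ccne1 (8.23), Ccne2 (5.43), Mcm3 (4.65) and Ccnb2 (3.28) lost in both. Circadian clock genes were marked at 15, 14 and 8 of 19, with the repressor gene Nfil3 (11.6) and the nuclear receptor gene Rora (4.65) lost in both. The siControl regions of Dlk1, Fosb and Nfil3 lay mostly outside the 1 kb window, and that of Fosb lay outside the gene. A narrower or shifted region would be called lost there, so these calls need not be losses of AcH3. With equal numbers of regions, siME2 losses were 10 against 7 for clock genes (2 within 10 kb) and 5 against 3 for insulin signalling.

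Genes of the deacetylase machinery were also among those marked by AcH3. Of 25 acetyltransferase and deacetylase genes, 21, 21 and 12 were marked, and Kat2a (10.6) was lost in both. Of 10 genes of the HDAC3 and NCoR complex, 9, 10 and 5 were marked. The siME2 losses in this list were 4, against 1 within 10 kb and 5 with equal numbers of regions. Hdac3 itself had folds of 11.1 in siControl and 7.82 in siME1 and no end region in siME2. Its corepressor partner Ncor1 was marked in all 3, with folds of 22.1, 16.9 and 3.67. Genes of other cell types were rarely marked: 0 of 20 neuronal genes in each library, 1, 0 and 0 of 20 hepatocyte genes, 3, 4 and 1 of 20 muscle genes, 2, 3 and 1 of 20 leukocyte genes, 1, 0 and 1 of 15 endothelial genes, and 2, 2 and 1 of 15 bone and cartilage genes. Apoa2 (8.60), an apolipoprotein gene of hepatocytes, and Spi1 (8.37), a transcription factor gene of leukocytes, were lost in both.

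Over all genes, the highest-scoring genes whose AcH3 end region was in siControl and in neither knockdown were Gm52051 (fold 21.9; chromosome 13, 98925210 to 98927087), Dip2b (17.1; chromosome 15, 100038608 to 100039811), Lemd2 (17.3), Gm41408 (14.2) and Skp1 (16.5), the last encoding a ubiquitin ligase subunit. Each of these siControl regions lay mostly outside the 1 kb window. At Dip2b, the gene end was at 100037626, so the region only touched the window. A narrower or shifted region in a knockdown would be called lost, so these calls need not be losses of AcH3. The highest-scoring genes with an AcH3 end region in both knockdowns and none in siControl were Gm38457, Spata4, Prss22, Kbtbd11 and Lrrc74a. All had an AcH2B end region in each of the 3 AcH2B libraries. The highest siControl scores were at Mdm2, Cwc22 and Ctcf. Mdm2 lay in a segment of chromosome 10 (117675543 to 117747540) where the background was 45.4 to 84.8 times that of the genome in 8 libraries. Cwc22 lay in one of chromosome 2 (77944232 to 78027159) with a background of 17.6 to 29.8 times in 7 libraries. Ctcf, which encodes an insulator protein, had folds of 25.2, 11.2 and 7.62.

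AcH2B differed in the other direction: it was listed at more gene ends in both knockdowns. End regions were found at 2214 genes in siControl, 6698 in siME1 and 5639 in siME2. Genes with an AcH2B end region in both knockdowns and none in siControl included Pparg, Cebpa, Lpl and Acsl1 of the adipocyte list, Acly, Fads1 and Fads2 of fatty acid synthesis, Me1 and Idh1 among NADPH producers, and Mtor, Tsc2, Gsk3b and Pik3r1 of insulin signalling. ChIP depth was close in the 3 libraries, with ratios to siControl of 0.997 and 0.965.

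In siME1, 4599 genes had gained and 115 had lost an AcH2B end region, so that 97.6% of the genes that differed were gained (97.1% to 98.0%). In siME2, 3771 had gained and 346 had lost one, or 91.6% gained (90.7% to 92.4%). Of the gained genes, 90.6% in siME1 and 95.1% in siME2 had an AcH3 end region in siControl, against 42.1% of all genes without an AcH2B end region in siControl. Simulated unchanged libraries lost on average 110 and 176 genes around the observed counts (at most 146 and 216) and 420 and 578 at 1 SD below them, so the 346 genes of siME2 lay between these settings. With equal numbers of regions, gained genes numbered 1812 and 2603 and the share gained was 81.4% in siME1 and 82.3% in siME2.

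**Figure D2:**
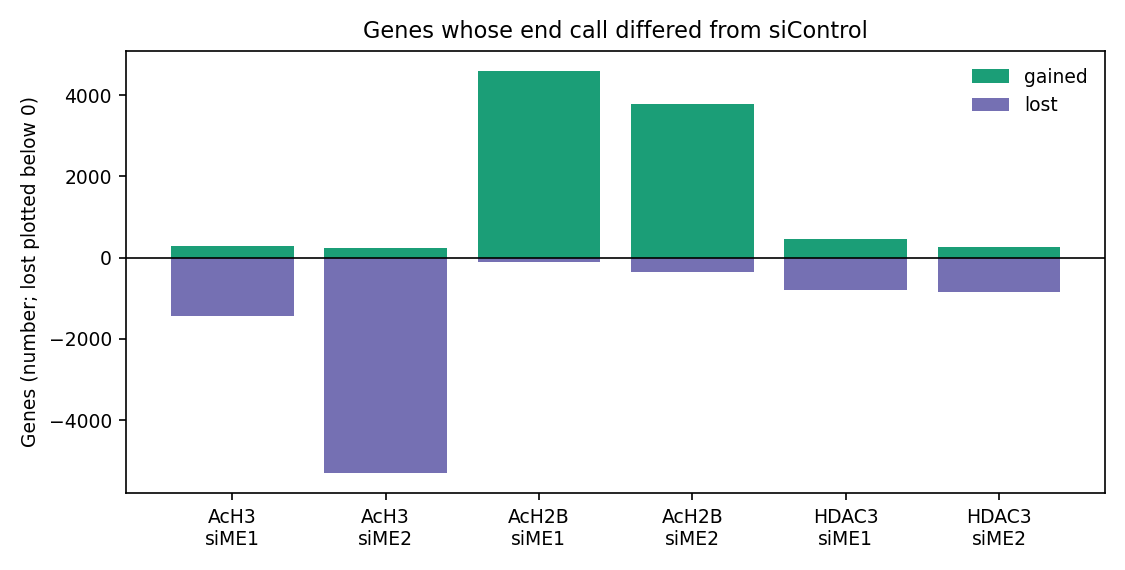
Genes (vertical axis, number) whose end call differed from the siControl library of the same antibody, for each antibody and knockdown (horizontal axis), with gained genes plotted above 0 and lost genes below. For AcH3, 5305 genes were lost in siME2 and 1446 in siME1, and for AcH2B, 4599 were gained in siME1 and 3771 in siME2.

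The AcH2B lists held 20046, 54649 and 32465 regions, or 2.73 and 1.62 times the siControl number, covering 12.6, 41.7 and 21.2 Mb. Median folds were 4.16, 4.002 and 4.17. Of the siControl regions, 87.2% overlapped a region of siME1 (86.7% to 87.6%) and 69.1% one of siME2 (68.4% to 69.7%), against 2.92% and 1.63% after rotation. The share of regions within 1 kb of a gene end was 13.3%, 15.9% and 20.4%. With reciprocal overlap of 50%, the shares of siControl regions found again were 27.4% and 33.5%, and siME2 then had the higher one.

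Insulin signalling genes and constitutively used genes were both marked by AcH2B in the knockdowns more often than lists matched on AcH2B siControl calls and scores. AcH3 was not matched. Of all genes gained, 90.6% in siME1 and 95.1% in siME2 had an AcH3 end region in siControl. So did 17 of 18 insulin signalling and 24 of 25 constitutively used genes. The percentiles in this paragraph therefore do not separate a list from AcH3-marked genes in general. Of 18 insulin signalling genes, 3 had an AcH2B end region in siControl, 14 in siME1 (percentile 100 of matched lists, median 6) and 12 in siME2 (percentile 99.98, median 5). Tsc2 had folds of 5.52 and 7.61 in siME1 and siME2, Mtor 5.41 and 5.44, and Gsk3b 4.81 and 4.39. These regions lay just outside the annotated gene spans. With no strand in the gene table, they cannot be told apart from regions of neighbouring genes. Of 20 NADPH-producing enzyme genes, 2, 10 and 9 were marked (percentiles 97.4 and 97.9), and Me1 (3.88 and 4.58), Idh1 (4.14 and 4.82), Pgls and Glud1 were gained in both. At equal numbers of regions, siME1 had 2 NADPH-producing genes gained and 2 lost, against 8 and 0, siME2 had 5 gained and 0 lost, against 7 and 0, and insulin signalling genes had 7 and 9 gained, against 11 and 9. For acetyltransferase and deacetylase genes, 4 gained and 1 lost in siME1 stood against 8 and 1, and 6 and 1 in siME2 against 9 and 0, while constitutively used genes had 7 and 2 against 9 and 1, and 10 and 0 in siME2 in both settings. Of 25 acetyltransferase and deacetylase genes, 7, 14 and 16 were marked (93.9 and 99.9), with Kat5, Kat8, Sirt7 and, at opposite gene ends, Hdac10 gained in both. Of 25 constitutively used genes, 8, 16 and 18 were marked (98.8 and 99.99), with Rpl4, Tubb5, Eef1a1 and Gusb gained in both.

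Of 34 adipocyte genes, 4, 12 and 9 carried an AcH2B end region in siControl, siME1 and siME2, at percentiles 68.9 and 44.9 of matched lists. Lpl had folds of 5.04 and 4.09 in siME1 and siME2, Cebpa 4.43 and 5.15, and Pparg 5.32 and 3.29. Fatty acid and triglyceride synthesis genes were marked at 4, 10 and 10 of 20, with the ATP citrate lyase gene Acly (3.06 and 7.15) gained and the elongase gene Elovl6 (siControl 3.91) lost in both. Cholesterol synthesis genes were marked at 4, 6 and 6 of 20, with Mvd and Hmgcs1 gained and Insig1 lost in both. NRF2 and redox genes were marked at 7, 12 and 9 of 19, with Nqo1 (4.60 and 4.81), Gclm and Txn1 gained in both. Mitochondrial genes were marked at 3, 9 and 7 of 20, with Cs and Acadvl gained in both. Genes gained and lost in siME1 with equal numbers of regions were 3 and 0 for the adipocyte list (8 and 0 for all regions), 1 and 1 for fatty acid synthesis (7 and 1), 1 and 2 for cholesterol synthesis (3 and 1), 3 and 1 for NRF2 and redox genes (5 and 0) and 0 and 0 for mitochondrial genes (6 and 0). In siME2 they were 2 and 0 (5 and 0), 5 and 1 (7 and 1), 3 and 2 (4 and 2), 1 and 2 (3 and 1) and 1 and 0 (4 and 0).

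Preadipocyte and fibroblast genes were marked by AcH2B in similar numbers in the 3 libraries, at 17, 16 and 16 of 24, with a siControl percentile of 100. Immediate early and inflammatory genes were marked at 13, 14 and 13 of 20, also with a siControl percentile of 100. In siME2, equal numbers of regions gave 0 gained and 3 lost for the preadipocyte list, against 0 and 1, and 0 and 4 for the immediate early list, against 0 and 0. The HDAC3 and NCoR list was marked at 4, 8 and 5 of 10, clock genes at 7, 11 and 7 of 19, where Dbp was gained in both, and cell cycle genes at 6, 10 and 9 of 22, where Cdk2 and Ccnd2 were gained in both. Cell cycle genes gained fell from 4 to 1 in siME1 and from 3 to 2, with 1 lost, in siME2 with equal numbers of regions. Genes of other cell types were marked at 0, 0 and 0 of 20 for neurons, 0, 0 and 0 of 20 for hepatocytes, 1, 3 and 1 of 20 for muscle, 0, 4 and 1 of 20 for leukocytes, 0, 1 and 0 of 15 for endothelium, and 2, 3 and 3 of 15 for bone and cartilage. Cd68, a leukocyte marker, was gained in both, through regions outside the gene that may belong to a neighbouring gene.

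**Figure D3:**
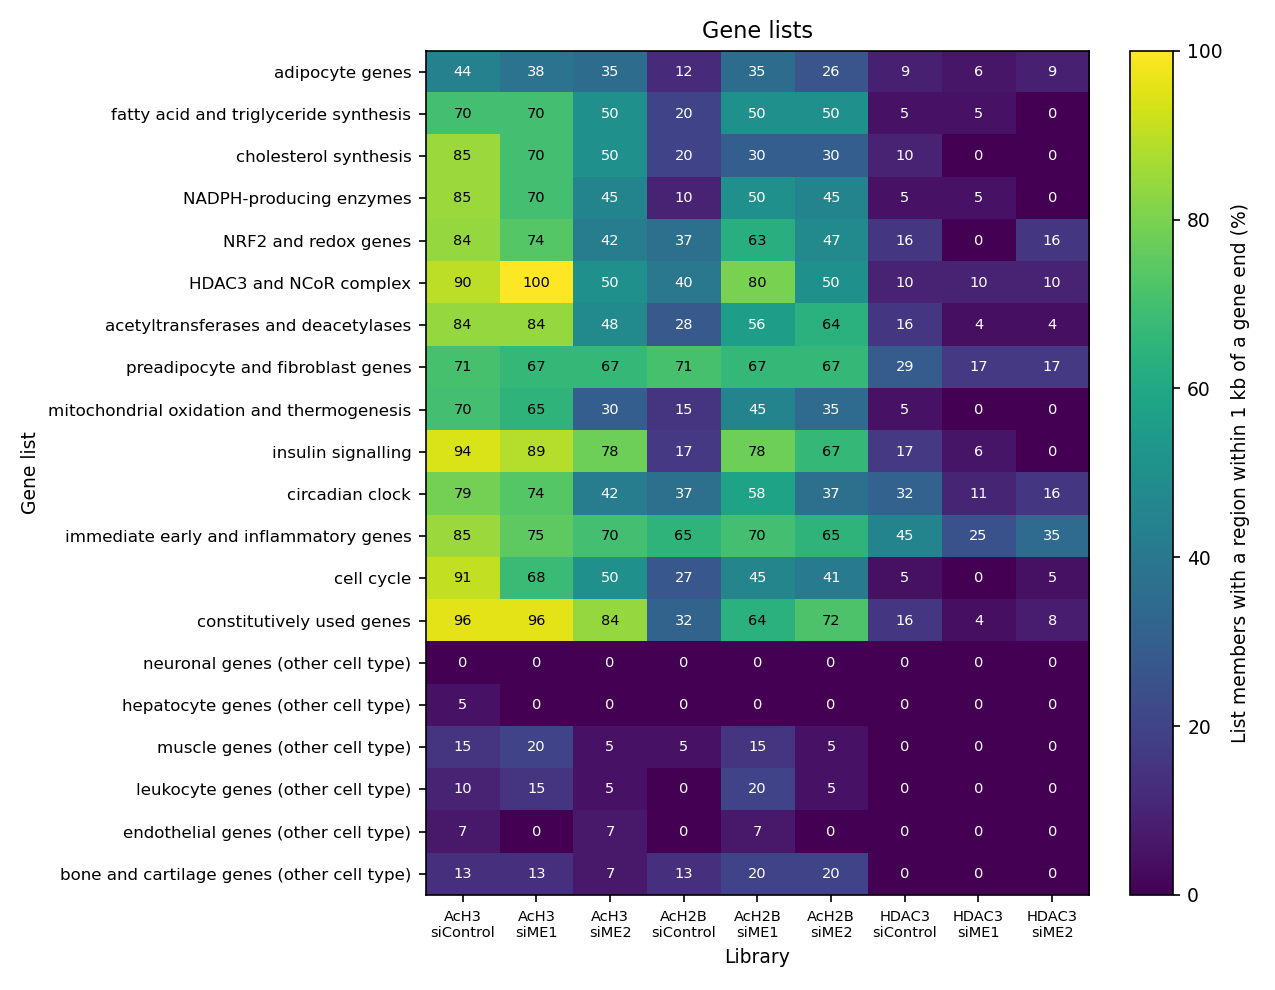
Share of the members of each gene list (rows) with a region within 1 kb of a gene end in each library (columns), in percent, by colour and number. Insulin signalling genes were marked by AcH2B at 16.7% in siControl, 77.8% in siME1 and 66.7% in siME2, and neuronal genes at 0% in all 9 libraries.

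Over all genes, the highest-scoring AcH2B gains in both knockdowns were at Mlec (8.74 and 9.62), Cdt1, a DNA replication licensing gene (8.80 and 9.98), Dazap2, Bccip and Arhgef10. The highest-scoring losses in both were at Knl1, Ror1, Srrm2, Slc14a2 and Plxdc1. The highest siControl scores were at 1700011L22Rik, Mdm2, in the high-background segment of chromosome 10, and Lrp6, a Wnt coreceptor gene.

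Regions in and around Pparg differed in number as well as at the gene end. From 10 kb before to 10 kb past the gene (chromosome 6, 115350879 to 115500404), AcH3 lists held 2 regions in siControl, 8 in siME1 and 11 in siME2. AcH2B lists held 7, 25 and 11 regions, and HDAC3 lists held 1, 1 and 0.

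**Figure D4:**
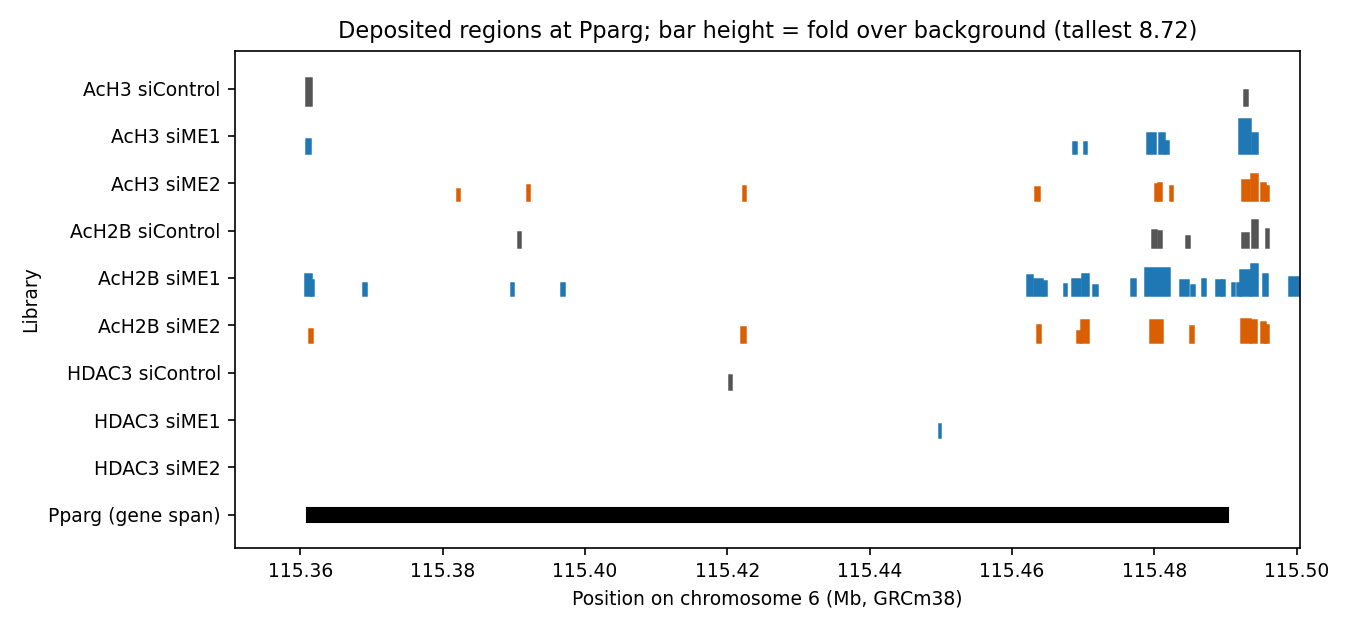
Deposited regions of the 9 libraries (vertical axis) along chromosome 6 (horizontal axis, Mb) around Pparg, whose span is the black bar, with bar height proportional to the fold over background of the region. AcH3 siControl had 2 regions and AcH2B siME1 had 25, and the tallest bar, with a fold of 8.72, was in AcH3 siME1.

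AcH3 and AcH2B lists overlapped more in the knockdowns than in siControl. In siControl, 29.7% of AcH3 regions overlapped an AcH2B region (29.1% to 30.3%), against 73.7% in siME1 (73.2% to 74.2%) and 61.2% in siME2 (60.6% to 61.8%). After rotation the shares were 1.11%, 2.87% and 1.57%, so that the observed shares were 26.7, 25.6 and 38.9 times the rotated ones, with no rise in siME1. In the other direction, 34.6%, 41.8% and 50.2% of AcH2B regions overlapped an AcH3 region. With equal numbers of regions, an alternative added after the data were seen, the shares were 29.7%, 56.1% and 52.7% for AcH3 on AcH2B and 34.6%, 52.1% and 52.8% for AcH2B on AcH3. Of the AcH3 regions that siControl lacked, 79.9% of 17646 in siME1 and 55.8% of 16883 in siME2 lay on an AcH2B region of the same siRNA. Over the 4673 regions shared by all 6 lists, the folds of AcH3 and AcH2B had a Spearman rho of -0.043 in siControl, 0.39 in siME1 and 0.46 in siME2, across regions, which are not independent replicates.

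HDAC3 was listed at fewer gene ends in both knockdowns. End regions were found at 992 genes in siControl, 654 in siME1 and 419 in siME2. Of the 992 genes, 716 had none in either knockdown, against 676 for independent lists, so loss in both was the common outcome. Among these were Hdac3 itself (siControl fold 3.74) and the acetyltransferase genes Ep300 (4.39) and Crebbp (4.14). They also included the cytokine genes Il6 (4.97) and Ccl2 (4.55), Pik3r1 (6.76), a regulatory subunit of PI3 kinase, and Cdk4 (6.54), a cell cycle kinase. The HDAC3 lists rest on weak enrichment: 375 of 4614 regions in siControl, 125 of 5202 in siME1 and 66 of 1597 in siME2 had a q under 0.05.

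In siME1, 798 genes had lost and 460 had gained an HDAC3 end region, so that 36.6% of those that differed were gained (33.9% to 39.3%). In siME2, 840 had lost and 267 had gained one, or 24.1% gained (21.7% to 26.7%). Simulated unchanged libraries, 1 SD below the observed counts, lost on average 534 and 580 genes. Of the siControl regions, 7.41% overlapped a region of siME1 (6.69% to 8.20%) and 5.74% one of siME2 (5.11% to 6.45%), against 0.195% and 0.064% after rotation. The ratios of region number to siControl were 1.13 and 0.346, and the first was 0.805 with the stricter limit. With equal numbers of regions, the share gained in siME2 was 50.7%, so that no net loss remained.

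By gene list, HDAC3 was most frequent at immediate early and inflammatory genes, with 9 of 20 in siControl (percentile 100), 5 in siME1 and 7 in siME2. Il6, Ccl2, Ier3 and Cxcl1 were lost in both, as were 716 of all 992 genes marked in siControl. Preadipocyte and fibroblast genes were marked at 7, 4 and 4 of 24, with Ddit3, Sox9 and Pdgfrb lost in both, and clock genes at 6, 2 and 3 of 19, with Per1, Nfil3 and Cry2 lost in both. Adipocyte genes were marked at 3, 2 and 3 of 34. Lpl had folds of 3.04 in siControl and 2.45 in siME1 and no end region in siME2, and Retn, which encodes resistin, was lost in both. Acetyltransferase and deacetylase genes were marked at 4, 1 and 1 of 25, with Ep300, Crebbp, Sirt7 and Sirt1 lost in both. Constitutively used genes were marked at 4, 1 and 2 of 25, with Ppia, Gapdh and Polr2a among those lost in both. The siME2 direction depended on list length: with equal numbers of regions, siME2 had 5 gained and 3 lost for immediate early genes (2 and 4 for all regions), 2 and 2 for preadipocyte genes (2 and 5) and 2 and 2 for clock genes (1 and 4). Within 10 kb, preadipocyte genes had 1 gained and 8 lost in siME2.

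The remaining lists had few HDAC3 end regions. They numbered 1, 1 and 0 of 20 for fatty acid and triglyceride synthesis (Scd2 lost in both), 2, 0 and 0 of 20 for cholesterol synthesis (Mvd and Msmo1), and 1, 1 and 0 of 20 for NADPH producers (Pgls). NRF2 and redox genes had 3, 0 and 3 of 19 (Srxn1 lost in both), and the HDAC3 and NCoR list 1, 1 and 1 of 10. Mitochondrial genes had 1, 0 and 0 of 20 (Cpt1a), insulin signalling genes 3, 1 and 0 of 18 (Pik3r1 and Akt1), and cell cycle genes 1, 0 and 1 of 22 (Cdk4). Equal numbers of regions left no cholesterol gene lost in either knockdown, and gave 1 gained and 1 lost in siME1 and 1 lost in siME2 for insulin signalling, and 1 lost in siME1 and 2 gained in siME2 for NRF2 and redox genes. No gene of the neuronal, hepatocyte, muscle, leukocyte, endothelial or bone and cartilage lists had an HDAC3 end region in any of the 3 libraries. Over all genes, the highest-scoring losses in both were at Mfsd5, Mdm2, Pik3r1, Cdk4 and Wls, and the gains in both at Lars2, Vps11, Spred2, Gm41291 and Mtdh, with the last pair sharing 1 region in each library. Lars2 (folds 2.10 and 3.31 at −log10 p of 6.11 and 11.5) and Wls (3.09 at 9.67) had low folds for their scores, as at a raised local background. In siME1, Vps11 had a fold of 4.21 at 5.72. The highest siControl scores were at Sppl3 (6.47), Mfsd5 (6.10) and Mdm2, in the high-background segment.

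HDAC3 regions lay on acetylated histones far more often than rotated regions did. In siControl, 36.2% of HDAC3 regions overlapped an AcH3 region (34.8% to 37.5%, 1.16% after rotation) and 24.6% an AcH2B region (23.4% to 25.9%, 0.821% after rotation). In siME1 the shares were 22.0% and 23.6%, and in siME2 36.0% and 35.3%. With a reciprocal overlap of 50%, which the narrow HDAC3 regions seldom reach, all 6 shares were between 2.06% and 5.82%. HDAC3 end regions in all 3 libraries were found at 70 genes, each with an AcH3 end region in siControl, among them Vim, Cebpb, Junb, Myc, Hes1 and Socs1, which were chosen after their values were seen.

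The siME1 and siME2 libraries shared many of their differences from siControl. For AcH3, 1322 genes were lost in both, against 745 for independent lists and at most 129 in the simulated unchanged libraries, and 140 were gained in both, against 5.71 (374 without high-background regions and 80 with equal numbers of regions). For AcH2B, 2651 were gained in both, against 882, and 67 lost in both, against 18.0 and simulated means of 28.5 around the observed counts (at most 53) and 223 at 1 SD below them. For HDAC3, 716 were lost in both, against 676 and simulated means of 54.1 and 370, and 31 were gained in both, against 5.88. Both knockdowns are set against 1 siControl library, so part of each excess may come from that library. With equal numbers of regions, the genes lost in both numbered 2179 for AcH3 and 301 for HDAC3, and the AcH2B genes gained in both numbered 982.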

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

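The depth, efficiency and siRNA tests, the second test of the AcH3 siME2 label, the overlap with equal numbers of regions and the split of the mixing tests by region strength were chosen after the result was seen. The simulations, the first label tests and the tests of mixing and of HDAC3 calls were written before their own values were computed.

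AcH3 and AcH2B end calls differed from siControl in opposite directions in both knockdowns. Of the genes that differed, 16.4% in siME1 and 4.22% in siME2 were gained for AcH3, against 97.6% and 91.6% for AcH2B, and the difference between the antibodies was not tested. A lower AcH3 depth is argued against by depth ratios to siControl of at least 1.09, a higher AcH2B depth by ratios of at most 0.997, and counting noise in the summit counts by at most 257 and 325 genes lost in simulated unchanged libraries, against 1446 and 5305 observed. The simulated regions kept their siControl coordinates, so losses through narrower or shifted regions are not covered. A lower AcH3 efficiency as the whole cause would remove regions everywhere, while regions away from gene ends were at least 2.16 times as many as in siControl (1.65 and 1.12 times with the stricter limit), but median folds fell from 5.82 to 4.34 and 4.19, so a part in the losses stays open. The siRNA treatment and any difference between cultures cannot be told apart with 1 library per antibody and siRNA, and mixing between antibodies, below, is also open.

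AcH3 and AcH2B lists were more alike in both knockdowns than in siControl, with 73.7% and 61.2% of AcH3 regions on AcH2B against 29.7%, and 41.8% and 50.2% of AcH2B regions on AcH3 against 34.6%, which with equal numbers of regions became 56.1% and 52.7% against 29.7%, and 52.1% and 52.8% against 34.6%. A wrong label on AcH3 siME1 is argued against by folds that followed AcH3 siControl more closely than any AcH2B library (difference in rho 0.111, SE 0.0249). For AcH3 siME2 the same planned test came out the other way (-0.271, SE 0.0242), as a wrong label would give. The AcH3 and AcH2B libraries of 1 siRNA appear to share a background library, which enters both folds and could raise their rho whatever the label. In siControl, where the background also appears shared, rho was -0.043. A second test, added afterwards for this reason, went against a library wholly of AcH2B. The rho of AcH3 siME2 with AcH3 siControl exceeded that of every AcH2B library by 0.232 (SE 0.0172). The 2 tests disagree, and a wrong label on AcH3 siME2 cannot be told apart from a difference between libraries. The SEs come from 200 bootstraps over chromosomes and do not cover differences between cultures. Mixing of material cannot be told apart from a treatment effect: of the strongest 10% of the other antibody's regions that had no siControl region of the tested antibody, 75.1% were called in AcH3 siME2, 75.8% in AcH2B siME1 and 67.2% in AcH2B siME2. No test of AcH2B material in AcH3 siME1 was run. Of the new regions of that library, 79.9% lay on an AcH2B siME1 region, so mixing there is open as well. The bound set beforehand, under 80%, was wrong as an exclusion, because calls fell to 27.0%, 54.7% and 32.1% in the weakest 10% and a small admixture could give such a fall, and 23.6% of the new AcH3 siME2 regions were in no AcH2B list, between the bounds set.

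Few HDAC3 siControl regions were found again in either knockdown. A candidate explanation is that most calls lay near the p threshold, since regions with a q under 0.05 were found again 3.46 times as often as the others (31.7% of 375 against 9.18% of 4239). Regions of high background do not account for those found again, of which they made up 7.68% of 508. The simulated unchanged libraries kept 41.9% and 36.8% of regions at 1 SD below the observed counts, more than the 7.41% and 5.74% observed. That setting takes every listed region as enriched, while 4239 siControl regions had a q above 0.05. It therefore cannot exclude false calls as a source of the turnover. No biological explanation was tested, as each group has 1 library.

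HDAC3 lists held summits on mitochondrial sequence, which the gene-end comparisons do not use: 36 in siControl, 34 in siME1 and 29 in siME2. They lay in 1, 7 and 11 regions, and summits of 1 region are not independent counts. The AcH3 and AcH2B lists held 0, but they were limited on q and the HDAC3 lists on p, so the numbers are not a like comparison. Summits on unplaced scaffolds numbered 76, 16 and 4 for HDAC3, 4, 7 and 8 for AcH2B and 8, 8 and 6 for AcH3.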

How the results depend on the processing

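The settings without high-background regions and with a region anywhere in the gene were added after the data were seen. Over all settings, the AcH3 share gained stayed under 50% and the AcH2B share above it in both knockdowns. Of the main values, which are region numbers, shares found again, gene-end calls and HDAC3 overlaps, 33 were within their limits, 65 moved and 4 were reversed. Of the other values, which are list member counts and locations, 179 were within their limits and 70 moved. Values are given in the order siME1, siME2, and the cause of a difference was not tested unless stated. With the stricter limit, the ratios of region number to siControl were 0.801 and 0.358 for AcH3 and 0.805 for HDAC3 siME1, each on the other side of 1. Shares of siControl regions found again were then 53.1% and 16.9% for AcH3, 84.2% and 64.1% for AcH2B and 5.55% for HDAC3 siME1, and shares gained were 3.22% and 0.784% for AcH3, 96.3% and 88.4% for AcH2B and 32.9% for HDAC3 siME1. With equal numbers of regions, shares found again were 60.7% and 41.6% for AcH3, 69.8% and 56.7% for AcH2B and 6.57% and 10.1% for HDAC3. Shares gained were 5.96% and 2.87% for AcH3, 81.4% and 82.3% for AcH2B and 50.7% for HDAC3 siME2, the last on the other side of 50%. Genes lost in both numbered 2179, 238 and 301 for AcH3, AcH2B and HDAC3, and genes gained in both 80 for AcH3 and 982 for AcH2B. HDAC3 regions lay on AcH3 at 43.6% in siControl and 26.5% in siME1, and on AcH2B at 28.8% in siControl and 30.2% in siME2. With reciprocal overlap of 50%, a stricter rule by construction, shares found again were 39.2% and 15.3% for AcH3, 27.4% and 33.5% for AcH2B and 3.19% and 2.77% for HDAC3. HDAC3 regions then lay on AcH3 at 2.75%, 2.06% and 5.82% in siControl, siME1 and siME2, and on AcH2B at 3.71%, 2.21% and 4.82%. Within 2.5 kb, shares gained were 20.3% and 5.23% for AcH3, 98.2% for AcH2B siME1 and 40.4% for HDAC3 siME1. Within 10 kb they were 29.7% and 8.36% for AcH3, 98.6% and 93.9% for AcH2B and 44.3% and 21.4% for HDAC3. With a region anywhere in the gene they were 27.9% and 8.52% for AcH3, 98.2% and 93.1% for AcH2B and 48.4% and 20.1% for HDAC3. Without high-background regions, shares found again were 69.1% and 44.4% for AcH3 and 80.03% and 66.9% for AcH2B, shares gained were 30.7% and 8.51% for AcH3 and 96.8% for AcH2B siME1, and 374 genes were gained in both for AcH3. Depth was within 1.29 times of siControl in every library, and the low number of HDAC3 regions with a q under 0.05 limits what that antibody can show. No paired analysis was possible because each antibody and siRNA has 1 library and no result comes from a test.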

Other observations

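The test of the adipocyte list was written before its own value was computed, after the values within 1 kb had been seen, and its AcH2B counterpart was weighed only after both values were seen.

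A small set of genes carried HDAC3 in every library. Of the siControl regions, 99 had a region of both knockdowns on them, and 70 genes had an end region in all 3 libraries. They included the transcription factor genes Cebpb, Fosl2, Bhlhe40, Junb, Myc, Hes1 and Klf10, and the signalling genes Dusp1, Socs1, Trib1 and Gadd45g, chosen after their values were seen. HDAC3 siControl regions on an AcH3 or AcH2B siControl region were found again in either knockdown at 19.9% of 2001, against 4.21% of 2613 on neither.

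In siControl, which was fixed 7 days after induction, adipocyte genes were not marked by AcH3 more often than random genes, with 15 of 34 at an end and 19 of 34 within 10 kb (percentile 44.4). Preadipocyte and fibroblast genes within 10 kb were at 22 of 24 (percentile 99.99). A hypothesis is that many of these cells may not have been differentiated adipocytes. The AcH3 value goes with it, while AcH2B at gene ends, with 4 of 34 (percentile 64.6), lies between the bounds set for AcH3. AcH2B within 10 kb, with 13 of 34 (percentile 99.5), goes against it, so the hypothesis is left open.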
